A study of Homo sapiens with 21 samples.

How the data were processed

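Peripheral blood leukocytes were separated on a density gradient and CD14-positive cells were taken by magnetic selection, per the labels' protocols. CD14 is a co-receptor for bacterial lipopolysaccharide and the usual surface marker of monocytes. Total RNA was labelled with biotin and hybridised to the Affymetrix human genome U133 array (chip A), a 1-colour array of short oligonucleotide probe sets. The 21 arrays came from 11 people described as caregivers and 10 described as controls, and the groups and numbers were read from the sample titles.

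The values were log2 expression levels as deposited by the authors, with 1 value per probe set and array. They had been made with RMA, per the submitters' processing notes, which give no version. RMA subtracts background, normalises the arrays to each other and summarises the probes of a set on the log2 scale. It narrows differences between weak probe sets, so small differences near the background can be understated. The scanner files were not used here, and signal over background per probe set was not analysed here. The median over the probe sets tested ranged from 5.40 to 5.61 between arrays, and no further normalization was applied. The number of arrays limits the precision of every value.

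The table held 22283 probe sets, of which 68 were Affymetrix control probe sets. The platform annotation, which can be old, gave 1 gene symbol to 19065 probe sets, several symbols to 1043 and none to 2107. Symbols were checked by Entrez gene ID against a RefSeq gene table. No symbol was updated, and the ID of 12 probe sets was not found in that table. Y-linked genes and X-inactivation transcripts, 52 probe sets, were left out of every test. Where a gene had several probe sets, as 4304 genes did, the probe set with the highest mean over all arrays was taken, which left 11939 genes. Probe sets with several symbols were not named. Coordinates were not used.

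Caregivers were compared with controls, always as caregiver minus control. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, without covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A further count took genes at an unadjusted p under 0.05 with a difference of at least 1.2-fold. The 22 gene lists were written before the data were examined. They covered glucocorticoid-induced genes, glucocorticoid receptor machinery, NF-kB targets, Toll-like receptor (TLR) and NF-kB signalling components, an inflammatory adversity profile, the type I interferon response, immediate early and AP-1 genes, cAMP and CREB targets, heat shock proteins, MHC class II presentation, oxidative phosphorylation, ribosomal proteins, the proteasome, and markers of classical and CD16-positive monocytes, T, NK and B cells, platelets, erythroid cells, neutrophils and dendritic cells. A list score was the mean over the measured genes of the list, 8 to 34 per list, of the log2 value minus the mean of that gene over all arrays. Scores were compared with a two-sided permutation test of 100000 resamples and adjusted over the 22 lists. The smallest p this test can give is 1e-05. Intervals at 95% came from 10000 bootstrap resamples of people. Where an array was left out and a group held fewer than 10 arrays, every split was enumerated. Covariates were entered by permuting residuals. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9. Limma's camera and fry served as alternative tests of the lists.

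RNA quality was measured per array as the log2 level of the 3-prime minus the 5-prime control probe sets of GAPDH and ACTB, averaged over both genes. Higher values mean shorter or more degraded RNA. The hybridization spike level was the mean of 9 probe sets and the polyA spike level that of 12. Array spread was the SD of the log2 values over all genes of an array. No batch, scan date or slide was used, and personal characteristics were not adjusted for. The titles number separate people, so the replicates are separate people.

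The named genes followed a rule fixed before the data were examined. With fewer than 6 genes past the threshold in a direction, it took the 6 with the smallest unadjusted p and at least 1.2-fold in that direction. It added up to 4 members per list with the smallest unadjusted p, and 19 genes of stress and inflammation whatever their values. Of these, PER1 and FCGR3A were not measured by a probe set with 1 symbol. This gave 104 measured genes, and 10 of them were read from probe sets whose suffix marks possible cross-hybridization. The alternatives concerned the choice of probe set, the filter on weak genes, the normalization, the variance model, covariates for RNA quality and other cell types, a block on the replicate number, and each array left out in turn. The remaining 4 were added after the data were seen, with array spread or hybridization spike level as a covariate and without 2 arrays with raised spikes or 5 arrays that correlated less with the rest.

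The gene test was run on simulated data for caregiver minus control, in which 200 of the 11939 genes were shifted. With the residuals of whole arrays shuffled, it recovered 70% of genes shifted 1.5-fold and 88.5% of those shifted 2-fold (medians of 20 simulations), with a median of 1 false call. With residuals drawn independently for each gene, it recovered 65.5% and 87% with a median of 7.5 false calls. For the list scores, a shift of 0.3 log2 reached an unadjusted p under 0.05 in 63.3% of the simulations over all lists, 0.6 log2 in 95.1% and no shift in 4.0%. For the NF-kB targets a shift of 0.3 was found in 16.0%.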

Results

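Genome-wide expression was measured in CD14-positive leukocytes, mainly monocytes, from the blood of 11 caregivers living under stress and 10 controls. Each of the 21 people contributed 1 array. The comparison asked whether gene expression in these cells differs between people in high-stress and in low-stress surroundings. Correlations between pairs of arrays ranged from 0.804 to 0.994 over genes, and no array was a copy of another.

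No gene passed the threshold, and the 6 genes with the smallest p and at least 1.2-fold in each direction are given with their values. LILRB1, an inhibitory leukocyte receptor for MHC class I, had a log2 level of 7.90 ± 0.17 (SD, n = 11) in caregivers and 8.25 ± 0.14 (SD, n = 10) in controls, a difference of -0.35 log2 that was -0.21 with repeated quantile normalization. GBP1, an interferon-induced GTPase, stood at 7.97 ± 0.85 and 9.13 ± 0.39, a difference of -1.16 log2 (SE 0.28) or 0.447-fold. TAP1, a subunit of the transporter that loads peptides onto MHC class I, differed by -0.73 log2 (SE 0.18), and the chaperone HSPH1 by -0.50 log2 (SE 0.12). On the lower side were also ARAP1, which regulates small GTPases (-0.52 log2), and the histone chaperone NAP1L4 (-0.33 log2). On the higher side in caregivers stood TESK2 (0.48 log2), IFT122 (0.43 log2), a protein of ciliary transport, the bile acid transporter SLC10A1 (0.39 log2), WFS1 (0.38 log2), the endocytic receptor CUBN (0.33 log2) and the neutrophil granule protein LTF (0.33 log2). Group means of these 6 genes were weak, from 4.85 (WFS1, controls) to 6.62 (SLC10A1, caregivers). The median probe set of an array lay at 5.40 to 5.61. Group means of the 6 lower genes ran from 6.70 (HSPH1, caregivers) to 9.13 (GBP1, controls). A weaker probe set of IFT122 differed by 0.06 log2, and the mean over its probe sets by 0.25. All 12 genes had an adjusted p of 0.266, the smallest limma gave.

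With limma, 0 of the 11939 genes passed the adjusted threshold, while 1898 had an unadjusted p under 0.05, where chance gives 597. Of these, 929 also differed by at least 1.2-fold, 354 higher and 575 lower in caregivers. Each array centred on its median gave 258 higher and 678 lower, and repeated quantile normalization gave 429 higher and 463 lower. When limma weighted the arrays by their quality, 1673 genes passed, 739 higher and 934 lower. With array spread as a covariate, chosen after the data were seen, 427 genes met the p and fold criteria, 232 higher and 195 lower, so that the excess of lower genes turned around. The count of 929 was 521 without caregiver 8, 617 without caregiver 5, 612 without control 8, 1518 without control 1 and 1562 without control 6.

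The sign of the difference followed the level of the gene. With the genes divided into 4 equal groups by mean level, the median difference was 0.06 log2 in the weakest, 0.10 in the next, 0.01 in the third and -0.14 log2 in the group of the most abundant genes. The share of genes with a higher mean in caregivers was 75.7%, 72.7%, 51.2% and 30.6% in the same order. The arrays of caregivers had a mean spread of 1.86 ± 0.10 log2 (SD, n = 11) and those of controls 1.92 ± 0.04 (SD, n = 10), with p = 0.0842 in a permutation test. The median level of the arrays was 5.49 ± 0.06 in caregivers and 5.45 ± 0.02 in controls (permutation p = 0.0307).

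Glucocorticoid-induced genes, which respond to cortisol, did not pass as a group. Their score differed by -0.04 log2 (95% interval -0.21 to 0.11), with p = 0.703 and adjusted p = 0.909. Of 28 measured members, 20 had lower and 8 higher means in caregivers, and 0 passed, over all genes or adjusted over the list alone. FKBP5, a co-chaperone of the glucocorticoid receptor that cortisol induces, stood at 5.47 ± 0.32 log2 (SD, n = 11) in caregivers and 5.85 ± 0.33 (SD, n = 10) in controls, a difference of -0.37 log2 (SE 0.14, adjusted p = 0.286 in limma). The transcription factor CEBPD differed by -0.59 log2 and STOM by -0.62, while MAOA differed by 0.21. TSC22D3, a glucocorticoid-induced leucine zipper protein, differed by -0.06 log2, the phosphatase DUSP1 by -0.08 and the haemoglobin scavenger receptor CD163 by -0.51. The receptor gene NR3C1 itself differed by -0.25 log2 (SE 0.20), and by -0.51 as the mean of its probe sets, -0.41 without control 1 and -0.07 with array spread as a covariate. As means of their probe sets, STOM differed by -0.31 log2, MAOA by 0.06 and TSC22D3 by 0.03. The score of the glucocorticoid receptor machinery differed by -0.13 log2 (adjusted p = 0.590), with HSP90AA1 at -0.35, STIP1 at -0.26 and HSD11B1 at 0.18. Without caregiver 6 the glucocorticoid-induced score differed by 0.02 log2, the machinery by -0.06, TSC22D3 by 0.07 and CD163 by -0.30. When array spread was a covariate, an alternative chosen after the data were seen, the same differences were 0.08, 0.05 and 0.23 log2, with DUSP1 at 0.08 and CD163 at 0.10.

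NF-kB target genes, which include most inflammatory cytokines, gave a score difference of -0.02 log2 (95% interval -0.49 to 0.42, adjusted p = 0.973). Of 34 measured members 18 had higher and 16 lower means in caregivers, and 0 passed, over all genes or adjusted over the list alone. The members went both ways. TNF stood at 8.09 ± 1.01 log2 (SD, n = 11) in caregivers and 9.17 ± 0.94 (SD, n = 10) in controls (difference -1.08 log2, adjusted p = 0.288 in limma), and the chemokine CCL4 differed by -1.27 log2 (adjusted p = 0.285). TNFAIP3, an inhibitor of NF-kB, differed by -0.31 log2. The chemokines CXCL8 and CCL2 differed by 0.28 and 0.30 log2, NFKB1 by 0.26, IL1B by 0.02, NFKBIA by -0.01, PTGS2 by -0.07 and IL6 by -0.22. Without control 6, IL6 differed by 0.46 log2, NFKB1 by 0.51 and PTGS2 by 0.20, without control 7 IL1B differed by -0.25 and PTGS2 by -0.42, and without caregiver 8 TNFAIP3 differed by -0.20 and CCL2 by 0.18. The scores of the controls had an SD of 0.68 log2 (n = 10). The score was 0.15 log2 without control 6 and -0.12 with array spread as a covariate. CXCL8 differed by 0.54 log2 as the mean of its probe sets.

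Other stress and inflammation lists did not pass either. The inflammatory adversity profile, a set of cytokine, AP-1 and NF-kB genes, scored 0.16 log2 higher in caregivers (adjusted p = 0.70), with 14 of 19 members higher, such as FOSB (0.85 log2), RELA (0.52 log2) and FOSL1 (0.47 log2). Its member with the smallest p, TNF, was on the lower side at -1.08 log2. Without control 6 the profile differed by 0.28 log2. All members but 1, PTGS1 at -0.25 log2, also belonged to other lists, so without shared genes the value was that of PTGS1. Targets of cAMP and CREB, which act downstream of beta-adrenergic signalling, differed by 0.29 log2 (95% interval -0.07 to 0.61, adjusted p = 0.390). Here 15 of 17 members had higher means in caregivers and 9 of 11 caregivers lay above the control median. The score differed by 0.39 log2 without caregiver 6 (permutation adjusted p = 0.222) and by 0.23 without caregiver 3. With array spread as a covariate, chosen after the data were seen, it differed by 0.42 log2 (permutation adjusted p = 0.331). VEGFA, an angiogenic growth factor, differed by 0.90 log2, SIK1 by 0.63, FOSL2 by 0.59 and the cytokine OSM by 0.35. Immediate early and AP-1 genes differed by 0.14 log2 (adjusted p = 0.590), although PPP1R15A stood at -0.49, KLF6 at -0.47 (-0.20 as the mean of its probe sets) and MYC at -0.37 log2. The 9 of its 22 measured members that belong to no other list differed by -0.08 log2. Heat shock proteins differed by -0.17 log2 (adjusted p = 0.562), with HSPH1 passing when adjusted over the list alone, HSPE1 at -0.44 (-0.27 without caregiver 6) and CRYAB at 0.29 log2. TLR and NF-kB signalling components, the receptors and kinases that sense bacterial products, differed by -0.15 log2 (p = 0.0449, adjusted p = 0.329), with 16 of 22 members lower. TLR1 differed by -0.68 log2, TLR8 by -0.55, the adaptor MYD88 by -0.32 and TLR4, the lipopolysaccharide receptor, by -0.31. This score was -0.10 log2 without caregiver 6. With array spread as a covariate, an alternative chosen after the data were seen, it was -0.03 log2 and the heat shock score -0.05. With repeated quantile normalization they were -0.09 and -0.11 log2.

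Type I interferon response genes had the lowest p among the 22 lists. Their score was -0.19 ± 0.34 log2 (SD, n = 11) in caregivers and 0.21 ± 0.39 (SD, n = 10) in controls, a difference of -0.40 log2 (95% interval -0.72 to -0.13) or 0.756-fold. Of 29 measured members 26 had lower means in caregivers, 7 of them at an unadjusted p under 0.05, and 10 of 11 caregivers lay below the control median. Besides GBP1, the antiviral enzyme OAS1 differed by -0.97 log2, IFI35 by -0.86 and BST2, which tethers budding viruses, by -0.69. The list did not pass (permutation p = 0.0136, adjusted p = 0.178), and GBP1 alone passed when adjusted over the list alone. Without caregiver 7 the list passed with adjusted p = 0.0172. Without control 6, whose score of 1.23 was the highest of the controls, the difference was -0.29 log2 (permutation adjusted p = 0.206). The highest adjusted p without 1 array was 0.332. Without the 5 arrays that correlated least with the rest (caregivers 5, 6 and 8 and controls 1 and 6), chosen after the data were seen, the difference was -0.16 log2.

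Markers of CD16-positive monocytes, a patrolling subset that carries little CD14 and would be partly lost in a selection for CD14, differed by -0.46 log2 (95% interval -0.80 to -0.14), from -0.22 ± 0.36 (SD, n = 11) in caregivers to 0.24 ± 0.45 (SD, n = 10) in controls. All 11 caregivers lay below the control median and 13 of 14 measured members had lower means, with LILRA1 at -0.95 log2, the receptor CSF1R at -0.80 and the cell cycle inhibitor CDKN1C at -0.76. The list did not pass (permutation p = 0.0162, adjusted p = 0.178), and LILRB1 passed when adjusted over the list alone. For LILRA1 and CDKN1C a weaker probe set pointed the other way, by 0.03 and 0.11 log2. Markers of classical monocytes differed by -0.33 log2 (adjusted p = 0.390), with the chemokine receptor CCR2 at -1.65 log2, PLBD1 at -0.65, S100A12 at -0.41, FCN1 at -0.29 and CD14, the protein used for the selection, at -0.84 log2 (SE 0.49). Adjusted for array spread, again chosen after the data were seen, the CD16-positive difference was -0.28 log2 and the classical difference -0.03 log2. With repeated quantile normalization, which gives all arrays the same spread, they were -0.40 and -0.28 log2. The classical difference was -0.22 log2 without caregiver 6 and -0.16 without the 5 arrays. CCR2 differed by -0.95 log2 as the mean of its probe sets, and CD14 by -0.21 with array spread as a covariate.

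**Figure D1:**
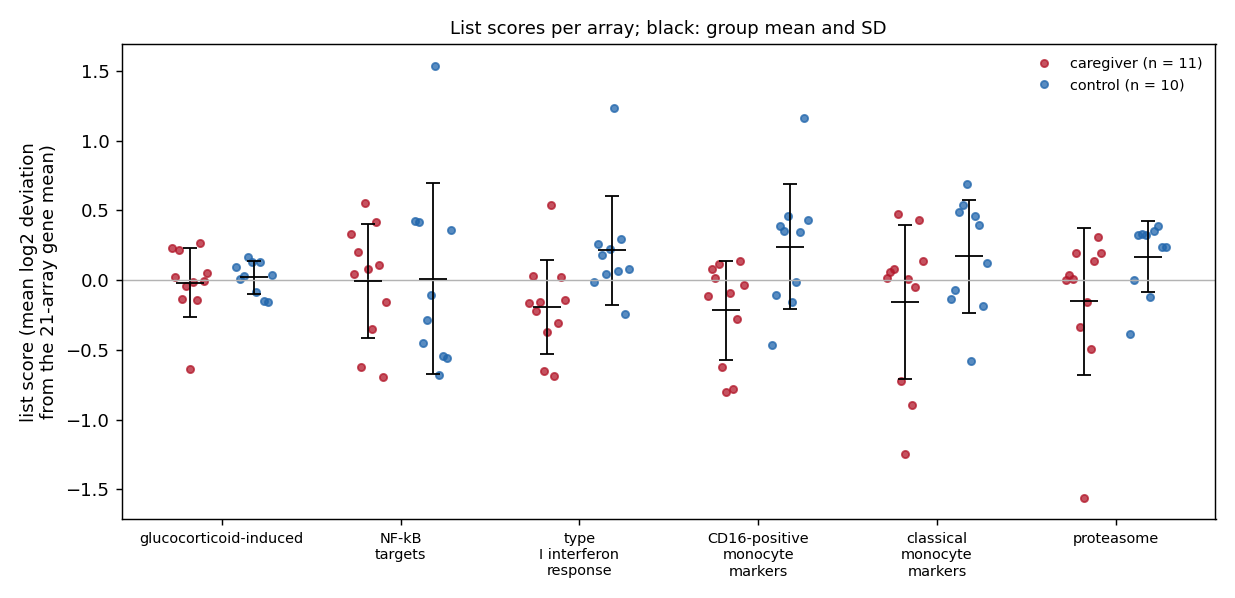
Scores of 6 gene lists (vertical axis, log2 deviation from the gene means over the 21 arrays) for each caregiver (red, n = 11) and control (blue, n = 10), with black bars for the group mean and SD. All 11 caregivers lie below the control median for CD16-positive monocyte markers and 10 of 11 for the type I interferon response, and the ranges of both groups overlap in all 6 lists.

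Lists of housekeeping machinery also had lower scores in caregivers without passing. Proteasome subunits differed by -0.32 log2 (95% interval -0.69 to -0.02, adjusted p = 0.390), with 24 of 25 lower, among them PSMD14 (-0.73 log2), PSMB5 (-0.66 log2, which passed when adjusted over the list alone), PSMA4 (-0.61 log2) and PSMD2 (-0.54 log2). Oxidative phosphorylation differed by -0.29 log2 (adjusted p = 0.390), with 23 of 26 lower, such as ATP5F1A (-0.91 log2), NDUFB8 (-0.44 log2), NDUFA9 (-0.41 log2) and NDUFV1 (-0.37 log2). Ribosomal proteins differed by -0.06 log2 (adjusted p = 0.797), with RPS19 at -0.28 log2 (-0.18 without caregiver 6). Without caregiver 6 the proteasome difference was -0.18 log2, that of oxidative phosphorylation -0.14 and that of ribosomal proteins -0.02, which was also its value without caregiver 7 or control 1. NDUFB8 differed by -0.18 log2 as the mean of its probe sets. The proteasome score followed array spread over the 21 arrays, with Pearson's r = 0.94 and Spearman's rho = 0.82 (permutation adjusted p = 5e-05 and 0.00022). Without the 2 arrays farthest from the median spread r was 0.79, and within groups it was 0.96 in caregivers and 0.77 in controls. Of the 22 lists tested this way, 10 correlated positively and 3 negatively with spread at an adjusted p under 0.05 for r, and 7 positively and 5 negatively for rho. Of the 13 called for r, 6 were not called without the 2 arrays farthest from the median spread. Their r without these arrays was 0.30 for glucocorticoid-induced genes, 0.25 for heat shock proteins, 0.47 for MHC class II and 0.46 for ribosomal proteins. It was 0.41 for CD16-positive monocyte markers and -0.45 for erythroid markers. Among these 6, rho over all arrays was called for glucocorticoid-induced genes (0.55), CD16-positive monocyte markers (0.64) and erythroid markers (-0.60). Spread is computed from the same values, so it is not independent of lists of abundant genes. Adjusted for array spread, the proteasome difference was -0.02 log2, that of oxidative phosphorylation 0.02 and that of ribosomal proteins 0.05. With repeated quantile normalization, which gives all arrays the same spread, they were -0.23, -0.20 and -0.03 log2, and none passed. The covariate therefore does not show that unequal spread accounts for these differences.

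**Figure D2:**
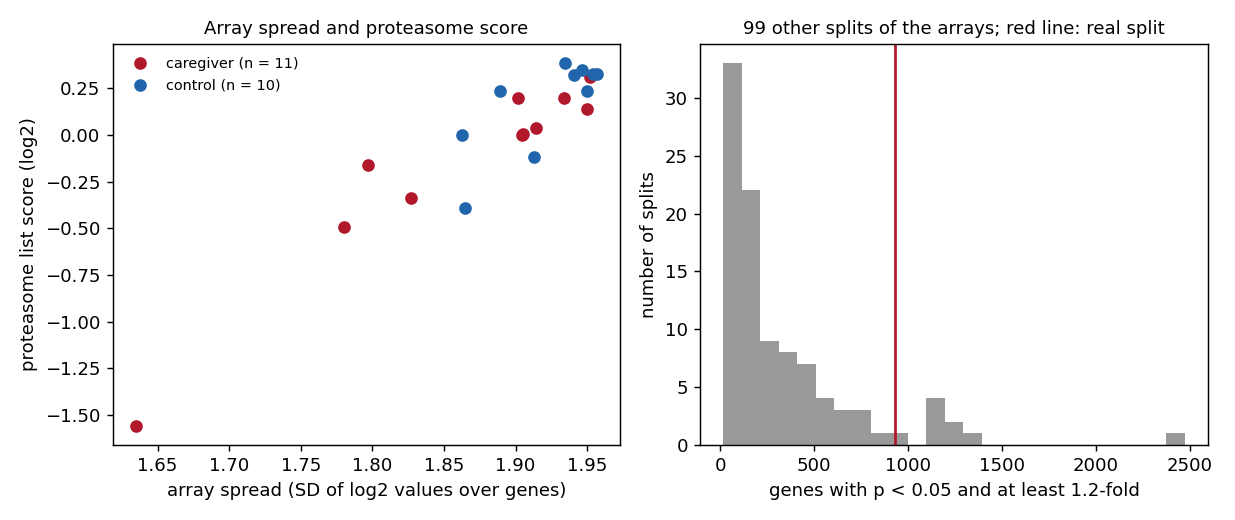
Left, the proteasome score (log2) of each caregiver (red, n = 11) and control (blue, n = 10) against array spread, the SD of the log2 values over genes, with r = 0.94. Right, the number of genes with p under 0.05 and at least 1.2-fold in 99 other splits of the arrays (grey bars, number of splits), with the real split at 929 as a red line and the highest other at 2472.

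The score of MHC class II presentation differed by 0.00 log2 (adjusted p = 0.973), with 6 of 13 members higher and HLA-DPB1 at -0.37 log2, HLA-DMB at -0.25, HLA-DRA at -0.17 and HLA-DOA at 0.10. Without caregiver 6 the score differed by 0.07 log2 and HLA-DRA by 0.06. With spread as a covariate the score differed by 0.15 log2 (permutation p = 0.0964), HLA-DRA by 0.18 and HLA-DMB by 0.05. CIITA, the activator of class II genes, differed by 0.18 log2 by its brightest probe set and by -0.52 log2 by another.

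No list of markers of cells outside the monocyte gate passed. T cell markers differed by 0.01 log2 (adjusted p = 0.973; CD5 0.27, CD27 0.17, CD28 0.15 and IL7R -0.29 log2) and platelet markers by 0.02 log2 (adjusted p = 0.973; SELP 0.14, MYL9 0.12, TUBB1 0.12 and SPARC -0.27 log2). NK cell markers differed by -0.06 log2 (adjusted p = 0.797), by 0.004 without control 9 and by -0.15 with array spread as a covariate. Among them the granule protein NKG7 stood at -0.65 log2 and passed when adjusted over the list alone, while GZMA stood at -0.34, PRF1 at -0.31 and NCAM1 at 0.26 log2. Without control 9, GZMA differed by -0.17 log2, PRF1 by -0.15 and the T cell marker IL7R by -0.15. B cell markers differed by 0.10 log2 (adjusted p = 0.903), with SPIB at 0.30, FCER2 at 0.25, IGHD at 0.17 and CR2 at 0.10 log2. The B cell score of caregiver 2 was 1.30, and without that array the difference was -0.03 log2. Erythroid markers differed by 0.15 log2 (95% interval -0.01 to 0.31, adjusted p = 0.390), and 10 of 11 caregivers lay above the control median, with SLC4A1 at 0.34, ALAS2 at 0.31, CA1 at 0.17 and AHSP at 0.15 log2, and the score differed by 0.06 with array spread as a covariate. Neutrophil markers differed by 0.03 log2 (adjusted p = 0.712), where LTF passed when adjusted over the list alone, CXCR1 stood at 0.20, PGLYRP1 at 0.24 and CXCR2 at -0.21 log2. Dendritic cell markers differed by 0.00 log2 (adjusted p = 0.973), where CD1B, at 0.29 log2, passed when adjusted over the list alone, CD1D stood at -0.66, CD1E at -0.16 and IRF4 at 0.13 log2. CD1B (5.33 in caregivers, 5.04 in controls) and NKG7 (5.08 and 5.72) were weak, near the median level of an array. Adjustment over a list alone does not count the other lists. Adjusted for array spread, T cell markers differed by -0.08 log2, platelet markers by -0.02, neutrophil markers by -0.03 and dendritic cell markers by 0.02. As means of their probe sets, CD28 differed by 0.05 log2, SPARC by -0.14, NCAM1 by 0.16, CA1 by 0.11 and CD1E by -0.03.

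**Figure D3:**
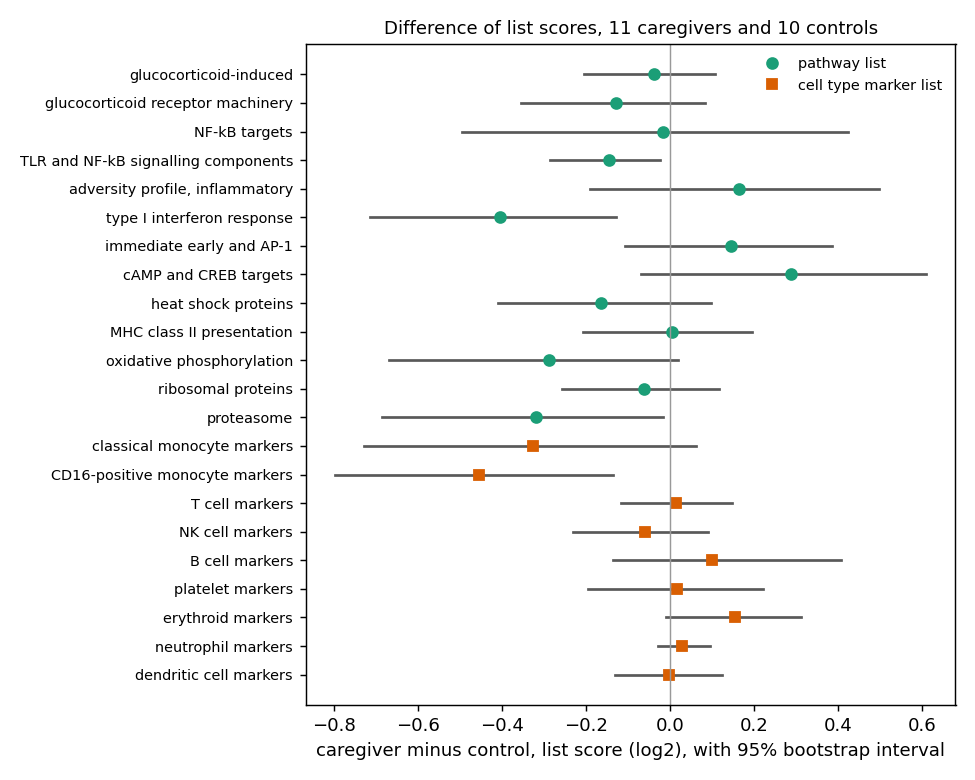
Difference of the list scores, caregiver minus control (horizontal axis, log2), with 95% bootstrap intervals as lines, for pathway lists (circles) and cell type marker lists (squares) in 11 caregivers and 10 controls. The type I interferon response (-0.40) and CD16-positive monocyte markers (-0.46) lie lowest, and none of the 22 lists passed after adjustment.

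Camera with its preset correlation called 7 of the 22 lists, namely the type I interferon response, the proteasome, CD16-positive and classical monocyte markers, oxidative phosphorylation, TLR and NF-kB components, all lower, and erythroid markers, higher. With an estimated correlation none passed: adjusted p = 0.428 for interferon, 0.255 for CD16-positive monocytes and TLR components, and 0.507 for the other 4. Fry called 0 lists. For NF-kB targets, immediate early genes, MHC class II and dendritic cell markers the mean, the median of the members and the camera direction did not share a sign.

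RNA quality gave no difference past the threshold. The log2 difference between 3-prime and 5-prime control probe sets of GAPDH and ACTB was 3.16 ± 0.75 (SD, n = 11) in caregivers and 3.19 ± 0.35 (SD, n = 10) in controls, with p = 0.942 in a permutation test. ACTB alone differed by 0.29 log2 and GAPDH alone by -0.34. Caregiver 6 stood at 5.34, with a median correlation with the other arrays of 0.846 and a hybridization spike level of 11.6 against a caregiver mean of 9.86. Control 1 shared the raised measures, at 4.12 for RNA quality and 11.1 for the hybridization spikes, and the polyA spikes stood at 8.54 in caregiver 6 and 7.87 in control 1. The labels used here give no batch, so it stays unknown whether these 2 arrays were processed together, and without both the RNA quality difference was -0.14 log2 (exact permutation p = 0.122). Without caregiver 6 the RNA quality difference was -0.24 log2 (permutation p = 0.0585).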

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

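Array spread as a covariate, the 5 arrays left out together and the CD16-positive minus classical score were chosen only after the results were seen. The RNA quality and NK cell covariates and each array left out in turn were planned, but their use as tests of an explanation was decided after the results were seen. Among the 10 controls, each value was checked for an array whose gap to its nearest neighbour took up an unusual share of the range. Chance marks about 1 in 20 such groups, and 23 of 134 values were marked. The 11 caregivers were too many for this rule and were not tested by it.

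Control 6 accounted for 7 marked values. Its level of IL6, an inflammatory cytokine, was 13.0 log2 against 5.34 to 8.18 in the other controls. CD14 stood at 9.41 against 11.4 to 12.7, RELA at 9.49 against 7.39 to 8.42, FOSL2 at 9.14 against 6.33 to 7.83, and the proteasome subunit PSMA4 at 8.71 against 9.38 to 9.89. The score of NF-kB targets was 1.53 against -0.68 to 0.42 and that of the type I interferon response 1.23 against -0.24 to 0.29.

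Control 9 had high levels of cytotoxic genes, with an NK cell score of 0.62 against -0.18 to 0.16, PRF1 at 7.90 against 5.92 to 6.57 and GZMA at 6.42 against 4.23 to 5.17. Control 10 had a MAOA level of 4.50 against 4.76 to 5.04.

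Control 1 accounted for 12 marked values, 4 of them array measures. Its RNA quality measure was 4.12 against 2.91 to 3.24, its ACTB measure 4.06 against 2.66 to 3.28, its hybridization spikes 11.1 against 9.35 to 10.2 and its polyA spikes 7.87 against 5.18 to 5.92. HSPE1 stood at 4.62, HLA-DPB1 at 10.9 and CXCR1 at 6.67, each below all other controls. HLA-DOA at 7.37, NDUFV1 at 9.46, ALAS2 at 6.31, CA1 at 6.18 and CD1E at 6.46 each lay above all other controls.

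The 929 genes past the p and fold criteria were weighed against chance, RNA quality and array spread. Of 100 splits of the arrays, the real one included, 10 gave at least 929 genes and the highest other gave 2472, so chance was not excluded. It was not excluded either for the 1673 genes with array weights, which 7 of 100 splits matched (highest other 3617), while for the count of 0 past the adjusted p the splits say nothing, since all 100 must reach 0 (highest other 61). RNA quality as a covariate left 1297 genes, which argues against RNA quality as the whole cause. Array spread as a covariate left 427, whereas repeated quantile normalization, which gives all arrays the same spread, left 892 (429 higher, 463 lower). Spread made equal thus removed most of the excess of lower genes but little of the count. Because these settings differ, how much of the count goes with uneven spread stays open. Over 99 other splits, the count and the size of the spread difference had Spearman's rho of 0.426. This lay between the bounds set beforehand for and against uneven spread as the source of large counts. A difference due to the stress of caregiving stays open and untested.

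The lower type I interferon score was weighed against array spread, single arrays and arrays that stand apart. With array spread as a covariate the difference was -0.36 log2 against -0.40, with permutation p = 0.0452, and without any 1 array the highest p was 0.0298 (without control 6, exact where a group fell below 10), which argues against either as the whole cause. Without the 5 arrays that correlated least with the rest it was -0.16 log2 (exact permutation p = 0.164), so these arrays may carry most of it. Chance among the 22 lists was not excluded (adjusted p = 0.178).

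The lower CD16-positive monocyte score was weighed against array spread, arrays that stand apart and NK cells, which also express CD16. With the NK cell score as a covariate the difference was -0.46 log2 (permutation p = 0.0217). The NK cell score itself differed by only -0.06 log2, so this covariate could move the difference little and does not decide on NK cells. Control 9 had the highest NK cell score of all arrays (0.62) and also the highest CD16-positive score (1.16). Without it the NK cell score differed by 0.004 log2 and the CD16-positive score by -0.35 log2, so this array carried part of the difference. The CD16 gene FCGR3A was not measured and is not part of the score. Without the 5 arrays the CD16-positive difference was -0.40 log2 (exact permutation p = 0.00622). Without any 1 array the highest p was 0.0360 (without control 9, exact). Both argue against these arrays as the whole cause. With array spread as a covariate the CD16-positive difference was -0.28 log2 (permutation p = 0.0865). With repeated quantile normalization, which gives all arrays the same spread, it remained at -0.40 log2 (permutation p = 0.0155). These settings differ, and spread itself was narrower in caregivers (1.86 against 1.92), so spread could not be fully told apart from a group difference. The CD16-positive minus classical score differed by -0.13 log2 (95% interval -0.49 to 0.17), too wide to say whether the subset shifted relative to classical monocytes. A biological difference between the groups stays open, as does an uneven loss of these cells, which carry little CD14, in the selection for CD14, which was not tested.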

How the results depend on the processing

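Signs of uncalled values are given as counts, except for the 2 main list scores and RNA quality. The count of genes past the adjusted p was 0 in every setting but limma with array weights (1673), in which 46 of 104 named genes passed. The count of 929 was 1471 over all probe sets, which tests more features, 618 among genes above the median level, which tests fewer, 2121 with array weights, 1532 with the NK cell score as a covariate and 427 with array spread. It ranged from 521 to 1562 when each array was left out in turn. Lists past the adjusted p numbered 0, except 7 with camera's preset correlation and 1 without caregiver 7 (0 to 1 over single arrays left out). The NF-kB targets score, -0.02, was 0.0128 with genes divided by their SD, 0.0005 among genes above the median, 0.0419 with repeated quantile normalization, 0.0006 with the NK score, -0.122 with array spread, 0.0199 without the 2 arrays with raised spikes and 0.0913 without the 5 low-correlation arrays, and -0.0935 to 0.153 over single arrays left out. The glucocorticoid-induced score, -0.04, was 0.0783 with array spread, 0.0317 without the 2 arrays and 0.0542 without the 5, and -0.0663 to 0.0236 over single arrays left out. The RNA quality difference, -0.02, was 0.29 for ACTB alone and -0.24 to 0.0791 over single arrays left out. The cause was not tested for these shifts, and no value of the 2 list scores or of RNA quality passed the threshold in any setting. Array spread, spike level and the arrays left out together were chosen after the data were seen. Named genes changed sign in 31 of 1531 values under other settings and 24 of 2184 without 1 array, and lists in 34 of 327 and 41 of 462. Of 63 further probe sets of named genes, 12 pointed the other way, 1 of them (CIITA) at an unadjusted p under 0.05. With the number as a replicate block (10 numbers, caregiver 11 left out), 0 genes passed and 1312 met the p and fold criteria. The deviations of same-numbered arrays correlated at -0.53 to 0.73, over 0.1 in 4 of 10, and 1 control correlated best with its own number. The expression values thus gave no sign of pairing by number. They cannot tell whether people were matched by number in the design. Signal over background limits weak genes and was not analysed here.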

Other observations

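In a list of interferon-gamma-induced genes, written after part of the results had been seen, 16 of 21 measured members had lower and 5 higher means in caregivers. The members named here fall outside the rule for named genes and were chosen after their values were seen. The immunoproteasome subunits PSMB8, PSMB9 and PSMB10 differed by -1.01, -0.65 and -0.49 log2, the peptide loading factor TAPBP by -0.37, the chemokine CXCL10 by -0.85 and the tRNA synthetase WARS1 by -0.45 log2, while the tryptophan-degrading enzyme IDO1 differed by 0.29 log2. CXCL10 and WARS1 varied more among controls (SD 1.34 and 0.61) than among caregivers (SD 0.38 and 0.27). The SDs of PSMB8, PSMB9, PSMB10, TAPBP and IDO1 were larger in caregivers. None of these genes passed in limma, with adjusted p from 0.266 for PSMB8 to 0.338 for PSMB10.

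GBP1 and TAP1, both induced by interferon-gamma, led to the hypothesis that such genes are lower in caregivers as a group. Both tests of it were chosen after the values of GBP1, TAP1, PSMB9 and CIITA and the type I interferon result had been seen. A list of 23 genes was written before its score was computed, and among its measured members 4 also belonged to other lists and 8 had an unadjusted p under 0.05 (6 lower, 2 higher). Without GBP1 and TAP1 the score was -0.13 ± 0.23 log2 (SD, n = 11) in caregivers and 0.15 ± 0.14 (SD, n = 10) in controls, a difference of -0.28 log2 (95% interval -0.44 to -0.13, permutation p = 0.00202, not adjusted for the 22 lists tested before it). Without PSMB9 and CIITA as well it was -0.29 log2 (permutation p = 0.00107). With array spread as a covariate it was -0.17 log2 (permutation p = 0.0123), which argues against uneven spread as the whole cause although the difference shrank, and without the 5 low-correlation arrays it was also -0.17 log2 (exact permutation p = 0.00093). The highest p without any 1 array was 0.00483 (exact where a group fell below 10). The values go with a lower interferon-gamma-induced group in caregivers, which remains a hypothesis, since it was found and tested on the same arrays. GBP1 was also in the type I interferon list, and no test told type I interferon and interferon-gamma apart.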
